A study of Mus musculus with 7 samples.

How the data were processed

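The series holds polyA RNA-seq libraries from cortical neurons of mouse embryos at E16.5, 3 from wild type mice and 4 from KAT7 mutant mice, all labelled male and of the C57BL/6 strain. The design text gives these as separate mice, so the replicates were taken as animals. The p-values of the tests of single genes measure the spread between animals of each genotype.

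The authors deposited a single table of whole-number read counts per gene for the 7 libraries, with an Entrez gene identifier and a gene length beside each row. The counts were made with featureCounts and the mouse assembly mm9 is named, per the submitters' processing notes. The aligner, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be separated here. The deposited gene length was used for a description of calls by length and in no test. Columns were matched to samples through the sample descriptions.

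Symbols were taken from an NCBI gene table of assembly GRCm38.p6 by Entrez identifier: 24176 of the 26286 identifiers (92%) had a symbol, and 652 tested identifiers had none. Because that assembly differs from mm9, it was used for names and for which genes lie next to each other, and no coordinates are given.

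Total counts were 8354636, 8731720 and 8813060 in wild type replicates 1 to 3 and 8522841, 8730911, 8491960 and 8272487 in KAT7 mutant replicates 1 to 4. Genes with low counts were removed with the filterByExpr function of edgeR by group (a minimum count of 10 in the smallest group's number of libraries, scaled to library size), which left 13681 genes. Library sizes were scaled by TMM factors, which were between 0.9894 and 1.01. Genotypes were compared with the quasi-likelihood F test of edgeR version 4.0.16 in R version 4.3.3, two-sided, in a model with genotype as the only term. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of KAT7 mutant over wild type with a standard error (SE) taken as the size of the fold change over the square root of F, and CPM are counts scaled to a common total with TMM-adjusted library sizes. The exact binomial interval for the Kat7 ratio has a confidence level of 95% and covers counting error only.

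Gene lists for cortical cell types, other brain regions, other cell types, cell processes, the KAT7 complex, RNA quality and sex were fixed before the data were examined, as were the test, the alternatives other than the one named below as added, and the rule for naming genes. The 35 lists with at least 3 tested members were tested with camera (limma version 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and the fry test were alternatives. For each list, counts of called members are given over all tested genes and adjusted over the list alone. The naming rule took Kat7, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean CPM of at least 1 in a genotype and no overlap between genotypes, leaving out predicted or unnamed genes, up to 4 called members of each list (up to 3 per direction where over 4 were called in both), or up to 2 of the most abundant members where none was called, and all tested members of the KAT7 complex and sex lists. Some genes that the rule names are not reported here. Genes outside this rule are marked as chosen after their values were seen.

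The fit was tested on simulated counts with the wild type means, the real library sizes and dispersions and 200 changed genes. The changed genes were drawn only from those above a minimum mean log2 CPM, so the rates below do not cover genes of low abundance. The data had a larger share of called genes (28.9%) than the simulation changed, so the rates may differ there. Of 50 genes changed at each size, edgeR called 44% at 1.25-fold, 78% at 1.5-fold, 92% at 2-fold and 98% at 4-fold among 13469 genes tested, and 6.6% of its calls were unchanged genes.

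Alternatives were RLE, upper-quartile or no composition factors, no count filter or a CPM of at least 1 in 3 libraries, DESeq2 version 1.42.0, limma-voom with and without quality weights, a robust edgeR fit, the replicate number as a block, blood genes left out, each library left out in turn, an adjusted p under 0.01 and an added 2-fold threshold. The KAT7 complex list without Kat7 was added after the data were seen. DESeq2 was run for genes and gives no list test here. All 35 splits of the 7 libraries into 3 and 4 were refitted.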

Results

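Gene expression was measured by RNA-seq in cortical neurons of E16.5 mouse embryos, 3 wild type and 4 KAT7 mutant. KAT7 is a histone acetyltransferase of the MYST family. Libraries held 8272487 to 8813060 counts, and 13681 of 26286 genes were tested. Pearson correlations of log CPM were 0.9906 to 0.9929 within genotypes and 0.9753 to 0.9785 between them, across genes that are not independent replicates. Pairs of libraries of a genotype differed by more than counting noise, with a chi-square per gene of 2.06 to 3.68, so none was treated as a repeated deposit of another.

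Kat7 itself was almost absent from the mutant libraries. Kat7 counts were 869, 848 and 854 in wild type replicates 1 to 3 and 3, 4, 3 and 10 in KAT7 mutant replicates 1 to 4. Summed over libraries, the mutant level was 0.592% of the wild type level (95% exact binomial interval 0.361 to 0.917). Kat7 fell from 98.9 ± 3.68 CPM (SD, n = 3) to 0.598 ± 0.420 CPM (SD, n = 4), a log2 fold change of -7.35 ± 0.15 (SE), with an edgeR adjusted p of 8.18e-18.

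The comparison of genotypes asks which transcripts differ in cortical neurons that lack most Kat7 mRNA. With a preset correlation, camera called the lists of synapse and ion channel, radial glia, telencephalon patterning and interferon response genes lower, and those of ventral telencephalon and of unfolded protein and integrated stress response genes higher. None of the 6 calls held with an estimated correlation (adjusted p = 0.198 to 0.727). For telencephalon patterning genes the estimate was 0.00108, below the preset 0.01. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1793 genes higher and 2163 lower in KAT7 mutant, 28.9% of those tested. Falls were larger: 518 genes fell and 150 rose by 2-fold or more, and 80 fell and 4 rose by 4-fold or more. Of the 2-fold changes, 304 falls and 93 rises lay in the lowest of 5 equal groups of tested genes by mean expression. Of all tested genes, 4832 (35.3%) had no overlap between genotypes, a pattern that chance gives in 5.7% of splits, and 3640 of these were among the 3956 called genes. The first principal component held 60.8% of the variance and separated the genotypes, with wild type libraries at -30.2 to -28.3 and mutant libraries at 20.6 to 22.9. On the second component KAT7 mutant replicate 1 lay at 23.1 and the other libraries at -9.8 to 1.6, and this library had the highest levels of the immediate early, stress response and ventral telencephalon lists.

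**Figure D1:**
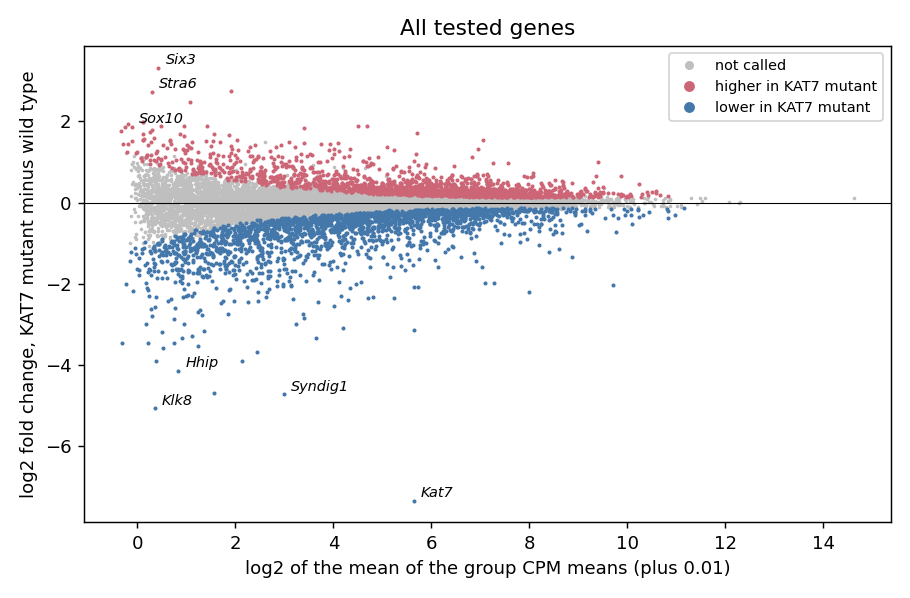
Each point is a tested gene, with the log2 of its mean CPM on the x axis and the log2 fold change of KAT7 mutant over wild type on the y axis. Red points are the 1793 genes called higher and blue points the 2163 called lower, and Kat7 lies lowest at -7.35.

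After Kat7, the largest falls among genes that the naming rule admits were in Klk8, a serine protease gene (-5.07 ± 0.57), and Syndig1, a synapse differentiation gene (-4.73 ± 0.24). Next came Cntnap5a, a contactin-associated cell adhesion gene (-4.69 ± 0.37), Hhip, a hedgehog-binding protein gene (-4.15 ± 0.41), and Fah, an enzyme of tyrosine breakdown (-3.91 ± 0.28). Syndig1 fell from 15.2 ± 1.72 CPM (SD, n = 3) to 0.561 ± 0.364 CPM (SD, n = 4), with an edgeR adjusted p of 1.67e-11. Panct2 (-3.91), the neuropeptide gene Nts (-3.68), the orexin receptor gene Hcrtr2 (-3.59), Slc7a14 (-3.55), Rxfp3 (-3.47) and Otogl (-3.47) completed the 12. Several were of low abundance, with wild type means of 2.47 CPM for Klk8, 2.43 for Panct2, 2.13 for Rxfp3 and 1.46 for Otogl. Klk8 had 0 to 0.122 CPM in the mutant libraries, so the sizes and order of such falls are uncertain. Without KAT7 mutant replicate 1 the value of Panct2 was -5.49.

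Of the 4 genes that rose by 4-fold or more, 2 were clone-named genes that the naming rule leaves out. Among genes that the rule admits, the largest rises were in Six3, a homeobox gene of the forebrain (3.33 ± 0.67), Stra6, a retinol transporter (2.73 ± 0.38), Timp4 (1.98), Prkg2 (1.98), the stress-induced transcription factor gene Atf3 (1.90), Cpxm2 (1.89), Nkd1, an inhibitor of Wnt signalling (1.89 ± 0.11), Arid5a (1.89), Sox10 (1.87), the somatostatin receptor gene Sstr3 (1.84), Ebf1 (1.79) and Glis3 (1.74). Most were of low abundance, and Six3 reached 2.44 ± 1.78 CPM (SD, n = 4) from 0.229 ± 0.194 CPM (SD, n = 3). Nkd1 rose from 9.57 ± 1.90 to 35.6 ± 1.93 CPM, with an edgeR adjusted p of 1.70e-10. Without wild type replicate 3, Six3 stood at 4.23 and Glis3 at 2.35. Ebf1 lost its call without wild type replicate 1 (1.57, edgeR adjusted p = 0.0678), without wild type replicate 3 (1.82, 0.0518) and in limma-voom with quality weights (1.19, 0.067), the adjusted p over all its alternatives being 0.000314 to 0.0678.

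**Figure D2:**
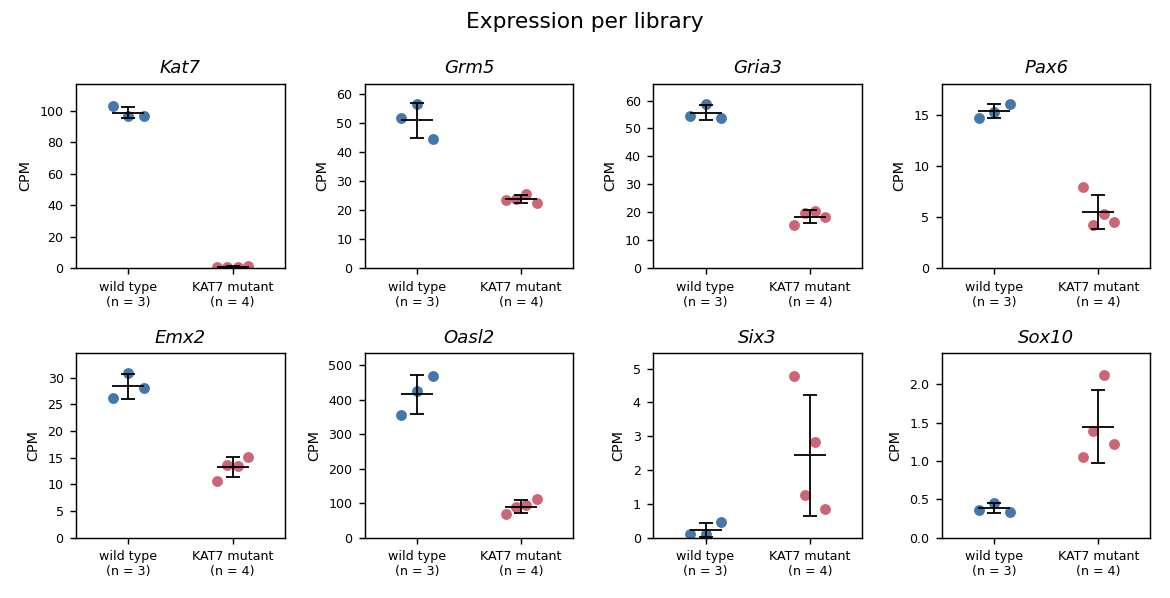
CPM of 8 genes in each library, with wild type in blue (n = 3) and KAT7 mutant in red (n = 4), the horizontal mark giving the mean and the bar the SD. Oasl2 has a mean of 416 CPM in wild type and 90.4 in KAT7 mutant, and mutant libraries spread widely for Six3.

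Synapse and ion channel genes included glutamate receptor subunits that fell by over 2-fold. Gria3 and Gria1, which encode AMPA receptor subunits, fell by 1.59 and 1.34 on the log2 scale, the metabotropic receptor gene Grm5 fell by 1.10, and the synaptotagmin gene Syt4 fell by 1.35, from 671 ± 37.5 CPM (SD, n = 3) to 263 ± 24.7 CPM (SD, n = 4). Of 26 tested members, 10 fell, 2 rose and 14 were not called, and 12 fell and 2 rose adjusted over the list alone. The median was -0.13 and the mean -0.30, with single members from -1.59 to 1.28. Camera gave an adjusted p of 4.95e-05 (adjusted p = 0.416 with an estimated correlation). A camera p as small was given by 2 of the 35 splits of the libraries into 3 and 4, the real one included.

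Radial glia and neural stem cell genes fell in 10 of 19 tested members and rose in 0, with 13 falling adjusted over the list alone. Pax6 fell by 1.48, Tnc by 1.37, Emx2 by 1.10 and Ptprz1 by 0.70 on the log2 scale. The list median was -0.51, with a camera adjusted p of 2.03e-05 (adjusted p = 0.416 with an estimated correlation), and 3 of the 35 splits gave a camera p as small. Among telencephalon patterning genes, which share Pax6, Emx2 and Id4 with that list, 9 of 12 fell, 0 rose and 3 were not called, and 1 rose without KAT7 mutant replicate 1, 3 or 4 and 2 without replicate 2. Lhx2 fell from 315 ± 12.4 to 201 ± 18.4 CPM. Adjusted over the list alone 9 fell and 1 rose, the median was -0.39 and the camera adjusted p was 8.41e-05 (adjusted p = 0.198 with an estimated correlation), a p that only the real split reached. The correlation estimated for this list, 0.00108, was below the preset 0.01, so a higher correlation does not account for the lost call.

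Interferon response genes fell in 8 of 11 tested members and rose in 0 (1 rise without wild type replicate 3), and the counts were the same adjusted over the list alone. Oasl2 fell by 2.20, Ifit1 by 1.64, Isg15 by 1.10 and Usp18 by 0.96 on the log2 scale. Oasl2 had 416 ± 56.5 CPM (SD, n = 3) in wild type and 90.4 ± 17.7 CPM (SD, n = 4) in KAT7 mutant. The list median was -0.73, and camera gave an adjusted p of 8.01e-07 (adjusted p = 0.416 with an estimated correlation). The members Rsad2 and Ifit3, chosen after their values were seen, were not called, with log2 fold changes of 0.09 and 0.26. Microglia and macrophage genes, another source of interferon-induced transcripts, rose in 4 and fell in 0 of 11 members, with 5 rising adjusted over the list alone, and included Csf1r at 1.05 and C1qb at 0.71. DESeq2 called 2 of the list higher, as did edgeR without wild type replicate 1, KAT7 mutant replicate 3 or KAT7 mutant replicate 4, and 1 fell without KAT7 mutant replicate 3. Their median was 0.35, with a camera adjusted p of 0.117, or 0.0466 without KAT7 mutant replicate 2, and 0.0466 to 0.246 over the refits.

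Interneuron and ventral telencephalon genes rose in 9 and fell in 1 of 17 tested members, and 10 rose and 1 fell adjusted over the list alone. The fall was not called by DESeq2, limma-voom or the robust edgeR fit, or with upper-quartile factors. It was also lost without wild type replicate 1 or KAT7 mutant replicate 2, 3 or 4. Gad2 and Gad1, the enzymes of GABA synthesis, rose by 0.76 and 0.70. Gad1 was not called by DESeq2 (adjusted p = 0.052) or the robust edgeR fit (0.116), in a range of 1.17e-14 to 0.116 over its alternatives. The median was 0.44 with a camera adjusted p of 0.00119 (adjusted p = 0.727 with an estimated correlation), and 13 of the 35 splits gave a camera p as small. Without KAT7 mutant replicate 1 the median was 0.288. The list varied within genotypes, with a mean level (log2 CPM relative to the 7-library mean) of 0.06, -0.28 and -0.42 in wild type replicates 1 to 3 and 0.41, -0.02, 0.21 and 0.03 in KAT7 mutant replicates 1 to 4. Oligodendrocyte lineage genes rose in 4 and fell in 1 of 10 members, the same adjusted over the list alone, and the camera adjusted p was 0.186 at a median of 0.36, which was 0.152 without KAT7 mutant replicate 3 and 0.202 without replicate 4. Olig2 rose by 1.67, Olig1 by 1.54 and Pdgfra by 1.07, while the myelin gene Cnp fell by 0.85. Of 10 striatal genes 3 rose and 4 fell, also over the list alone, and only 1 rose without KAT7 mutant replicate 1 or without replicate 3. Drd1 rose by 1.12 and Penk fell by 2.00. Their median was -0.01 (-0.305 to 0.103 with 1 library left out) and mean 0.36, camera put them as higher, and its adjusted p was 0.981.

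Unfolded protein and integrated stress response genes rose in 6 and fell in 0 of 14 tested members (1 fall without KAT7 mutant replicate 1), and 8 rose and 1 fell adjusted over the list alone. Sesn2 rose by 1.21, and Psat1 and Asns, enzymes of serine and asparagine synthesis, rose by 0.88 and 0.49. The median was 0.33, with a camera adjusted p of 0.0012 (adjusted p = 0.727 with an estimated correlation), and 9 of the 35 splits gave a camera p as small. The mean level of the list (log2 CPM relative to the 7-library mean) was -0.13, -0.37 and -0.36 in wild type replicates 1 to 3 and 0.50, 0.23, 0.09 and 0.04 in KAT7 mutant replicates 1 to 4. That of immediate early genes was 0.92 in KAT7 mutant replicate 1 against -0.36 to -0.07 in the other mutant libraries. In wild type replicates 1 to 3 it was 0.26, -0.17 and -0.48, so replicate 1 was the highest of each genotype for both lists. Jun, the only called member of 10 tested immediate early genes, rose by 0.47, or by 0.27 without KAT7 mutant replicate 1, and was not called by DESeq2 (adjusted p = 0.0908) or the robust edgeR fit (0.171), in a range of 3.32e-11 to 0.171 over its alternatives. KAT7 mutant replicate 1 also had the highest Atf3 (6.78 CPM) and Arid5a (62.4 CPM). The immediate early list had 1 rise and 0 falls, also adjusted over the list alone, with 2 rises without wild type replicate 1 or KAT7 mutant replicate 3, 3 without KAT7 mutant replicate 2, 4 without replicate 4, and 1 fall without replicate 1. It had a median of 0.26 (-0.0762 to 0.471 with 1 library left out) and a camera adjusted p of 0.46.

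**Figure D3:**
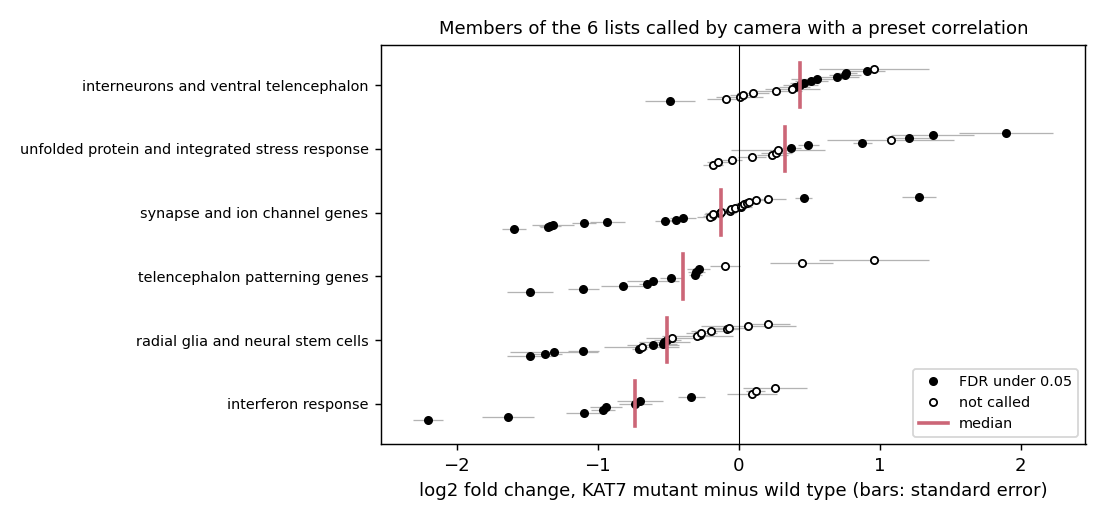
Log2 fold changes of KAT7 mutant over wild type (x axis) for each tested member of the 6 lists called by camera with a preset correlation. Filled points passed the edgeR threshold, open points did not, grey bars are SE and red lines are list medians, from -0.73 for interferon response genes to 0.44 for interneuron and ventral telencephalon genes.

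Camera called these 6 lists of 35 at the preset correlation. With an estimated correlation camera called 0 lists after adjustment, with 3 at an unadjusted p under 0.05, and fry called 11. Fry, which does not compare a list with other genes, gave an adjusted p of 0.00228 for telencephalon patterning, 0.00529 for radial glia and 0.00757 for synapse and ion channel genes. Its adjusted p was 0.00944 for interferon response, 0.0411 for stress response and 0.108 for ventral telencephalon genes. Camera at the preset correlation called at least 6 lists in 19 of the 35 splits of the libraries into 3 and 4, so the number of lists called does not set the genotypes apart.

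Genes of cortical layers were called in both directions. Deep layer genes rose in 8 and fell in 4 of 16, with 8 and 5 adjusted over the list alone, and 5 rose without wild type replicate 2. Tbr1 rose from 340 ± 29.9 to 483 ± 17.8 CPM, Foxp2 rose by 1.00 and Pcp4 by 0.78, and Crym fell by 0.75. The median was 0.16, and the camera adjusted p was 0.268, or 0.0432 without wild type replicate 3, and 0.0432 to 0.384 over the refits. The median was 0.0832 without KAT7 mutant replicate 1 and 0.0992 without replicate 2. Upper layer genes rose in 3 (5 without KAT7 mutant replicate 1) and fell in 7 of 15, with 5 and 7 over the list alone, at a median of -0.09 and a camera adjusted p of 0.329. Plxnd1, a semaphorin receptor, rose by 1.53, whereas Pou3f3 fell by 0.56, Pou3f2 by 0.84 and Lmo4 by 0.93. Among axon guidance genes, 7 rose and 8 fell of 23, with 9 and 9 over the list alone. Sema3c fell by 1.14, Nrp1 by 0.77 and Robo2 by 0.71, and Ntn1 rose by 1.32. Their median was 0.00, with a sign that turned negative under upper-quartile factors and library size only, and the camera adjusted p was 0.719.

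Pan-neuronal genes rose in 6 and fell in 5 of 20 (3 without wild type replicate 1), with 7 and 7 adjusted over the list alone, at a median of -0.05 (-0.0651 to -0.0237 with 1 library left out) and a camera adjusted p of 0.398. Stmn2, a microtubule regulator of growing axons, fell from 1334 ± 36.5 to 328 ± 28.0 CPM, a log2 fold change of -2.02 ± 0.06 (SE) with an edgeR adjusted p of 1.51e-15. Rbfox3 rose by 0.45, Elavl4 by 0.44 and Elavl3 by 0.18, and Nefl fell by 0.34 and Tubb3 by 0.21. Intermediate progenitor genes rose in 3 and fell in 4 of 13, also over the list alone, with Rhbdl3 at 0.85 and Insm1 at -0.39. Their median was -0.04 (-0.21 to -0.000443 with 1 library left out) and mean 0.02, camera put them as lower, and its adjusted p was 0.955. Subplate genes rose in 2 and fell in 0 of 7, also over the list alone, including Nxph4 at 0.45, and only 1 rose without wild type replicate 3, by DESeq2 and in the robust edgeR fit. Their median was 0.13, from 0.0757 without KAT7 mutant replicate 1 to 0.306 without replicate 3, and the camera adjusted p was 0.398. Cajal-Retzius genes rose in 3 (1 without wild type replicate 2) and fell in 1 of 9, also over the list alone, with Ebf3 at 0.86 and Calb2 at -1.22. Their median was 0.03 (-0.18 to 0.254 with 1 library left out) and mean -0.01, camera put them as higher, and its adjusted p was 0.839.

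Of the lists of other regions and cell types, camera called only that of interneurons and ventral telencephalon at the preset correlation, and none with an estimated correlation. Cortical hem and hippocampal genes rose in 1 and fell in 3 of 9, with 2 and 4 over the list alone, including Prox1 at -1.11 and Dkk3 at -1.03. Without wild type replicate 3 the counts were 2 and 5, and without KAT7 mutant replicate 1 there were 2 rises. Their median was -0.44 and the camera adjusted p 0.355, or 0.0432 without wild type replicate 3, and 0.0432 to 0.61 over the refits. The median was -0.265 without KAT7 mutant replicate 1. Astrocyte genes rose in 1 and fell in 6 of 13, also over the list alone, with Sparcl1 at 1.13, Gfap at -1.70, Aldoc at -0.97 and Slc4a4 at -0.83. The median was -0.05 (-0.108 to -0.00406 with 1 library left out) and the camera adjusted p 0.803. Endothelial genes rose in 1 and fell in 2 of 7, with 2 and 2 over the list alone, including Ramp2 at -1.27 and Slco1c1 at -0.89, a median of 0.00 (below 0 under upper-quartile factors and library size only), a mean of -0.13 and a camera adjusted p of 0.955. Endothelial rises were 0 without wild type replicate 1 and 2 without KAT7 mutant replicate 4. Of 3 tested pericyte genes Pdgfrb fell by 0.73, and of 3 choroid plexus genes Enpp2 fell by 1.48, with 1 fall also over each list alone and camera adjusted p of 0.768 and 0.955. The pericyte median was -0.02 (-0.327 to 0.00451 with 1 library left out), with 2 falls without wild type replicate 3, and 1 choroid plexus gene rose without wild type replicate 3 or KAT7 mutant replicate 3. The choroid plexus median was 0.19 and its mean 0.07, while camera put it as lower. Meningeal genes had 0 rises and 1 fall of 4 (0 without wild type replicate 1 or KAT7 mutant replicate 1), also over the list alone, a median of 0.06 (-0.0164 to 0.125 with 1 library left out), a mean of 0.00 with a camera direction of lower, and a camera adjusted p of 0.955. Thalamic genes had 0 rises and 1 fall of 3, with 1 and 1 over the list alone, and a camera adjusted p of 0.839 at a median of -0.27 (-0.34 to 0.104 with 1 library left out). The thalamic fall was not called without wild type replicate 1 or 2 or KAT7 mutant replicate 2, and 2 rose without wild type replicate 3 and 1 without KAT7 mutant replicate 1. Of 5 tested blood genes 0 were called by edgeR, also adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 called by DESeq2 and 2 by limma-voom, at a median of 0.66 and a camera adjusted p of 0.293. Without wild type replicate 1 5 blood genes rose, the median was 1.72 and the camera adjusted p 0.000139, with 0.000139 to 0.672 over the refits, and without KAT7 mutant replicate 2 there was 1 rise. Over the libraries left out the lowest blood median was 0.282. Hba-a2 stood at 26.2 ± 23.9 CPM (SD, n = 3) in wild type and 41.2 ± 20.4 CPM (SD, n = 4) in KAT7 mutant, and was called without wild type replicate 1 (1.72, edgeR adjusted p = 0.000306) and with no count filter (0.66, 5.39e-06). No Hox or posterior patterning gene had enough counts to be tested (0 of 21).

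DNA replication genes fell in 5 and rose in 0 of 19, with 4 falling over the list alone, and Ccne1 fell by 0.83, Mcm2 by 0.70 and Mcm3 by 0.62. The count was 3 by DESeq2 and without wild type replicate 2 or 3 or KAT7 mutant replicate 2 or 4, and 1 rose without KAT7 mutant replicate 1. Mitosis genes fell in 4 and rose in 0 of 19, with 1 falling over the list alone, and Ube2c fell by 0.56. Only 1 mitosis gene was called by DESeq2, without wild type replicate 3 and without KAT7 mutant replicate 2, and 2 without wild type replicate 1 or KAT7 mutant replicate 4. Camera adjusted p was 0.398 at a median of -0.15 for DNA replication (-0.244 without wild type replicate 1) and 0.293 at a median of -0.23 for mitosis. P53 targets rose in 2 and fell in 4 of 16, with 3 and 5 over the list alone, with a camera adjusted p of 0.657 at a median of -0.14. They included Sesn2, shared with the stress response list, at 1.21, Plk2 at -0.39, Eda2r at -1.02 and Pmaip1 at -1.23. Hypoxia and glycolysis genes fell in 6 and rose in 0 of 14, with 6 and 1 over the list alone, and 1 rose without wild type replicate 1 or 3 or KAT7 mutant replicate 1. Ldha fell by 0.60, Bnip3 by 0.83 and Ndrg1 by 0.41. Their median was -0.08, or -0.019 without wild type replicate 1, and the camera adjusted p 0.254. Cholesterol synthesis genes rose in 1 and fell in 4 of 16, also over the list alone, including Mvd at -0.39 and Nsdhl at -0.23, with a median of -0.10 and a camera adjusted p of 0.447. Only 2 fell without wild type replicate 2, and the rise was not called by DESeq2, with library size only, or without any 1 library other than KAT7 mutant replicate 1.

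Of 9 tested partners of KAT7, 5 rose. The scaffold genes Brpf1, Brd1 and Brpf3 rose by 0.30, 0.28 and 0.45. Jade2 rose by 1.08 and Jade3 by 0.31, and both calls were lost without wild type replicate 2 and without KAT7 mutant replicate 4. Jade2 had edgeR adjusted p of 0.0682 and 0.0597 in those fits and 0.0612 without wild type replicate 3, and Jade3 had 0.167 (at a log2 fold change of 0.21) and 0.0659. Over all alternatives the adjusted p was 0.000298 to 0.0682 for Jade2 and 0.00833 to 0.167 for Jade3 by edgeR, DESeq2 or limma. Jade1 at 0.72, Ing4 at -0.07, Ing5 at -0.09 and Meaf6 at -0.09 were not called. Jade1 passed without wild type replicate 1 (edgeR adjusted p = 0.0331) and without KAT7 mutant replicate 3 (0.0352), in a range of 0.0331 to 0.269. Of 10 complex members 5 rose and 1 fell, with 6 and 1 adjusted over the list alone. The median was 0.29 but the mean was -0.45 and camera put the list as lower, because Kat7 is a member, with an adjusted p of 0.081, or 0.0424 without wild type replicate 2 and 0.0193 with no count filter, in a range of 0.0193 to 0.371. In the list without Kat7, chosen after the data were seen, camera put the 9 members as higher, with an adjusted p of 0.117 (adjusted p = 0.487 with an estimated correlation). Of the 4 tested MYST paralogs 0 were called by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, and 1 had an unadjusted p under 0.05, with Kat6a at 0.03 and Kat6b at 0.14, a median of 0.04 (0.00394 to 0.0643 with 1 library left out) and a camera adjusted p of 0.719. Kat6b lay near the threshold (edgeR adjusted p = 0.0551) and passed without KAT7 mutant replicate 3 (0.02), with RLE factors (0.0489), in the robust fit (0.0497) and in limma-voom with quality weights (0.0491), in a range of 0.02 to 0.173. Other histone acetylation enzymes rose in 4 and fell in 3 of 18, also over the list alone, including Sirt1 at 0.42 and Ep300 at 0.26, with a median of 0.02 (-0.0496 to 0.0528 with 1 library left out) and a camera adjusted p of 0.678. Of their falls 0 were called without wild type replicate 1 or 2 or KAT7 mutant replicate 2, and 1 without KAT7 mutant replicate 1 or 4, by DESeq2, by limma-voom and with RLE factors.

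Cytosolic ribosomal protein genes rose in 4 and fell in 2 of 83, with 2 and 1 over the list alone, and Rps26 rose by 0.24 while Rps4l fell by 1.53. Rises were 1 without wild type replicate 2 and 2 without wild type replicate 3 or KAT7 mutant replicate 2 or 3, and falls were 1 without wild type replicate 3 or KAT7 mutant replicate 3. The median was 0.05 (0.027 to 0.0596 with 1 library left out) and the camera adjusted p 0.398. The table held 0 mitochondrially encoded genes. Xist had 1 to 8 counts per library. The Y-linked genes Kdm5d (36.2 and 34.6 CPM in wild type and KAT7 mutant) and Uty (20.1 and 21.2 CPM) were present in every library, and Ddx3y rose by 0.45 and Eif2s3y by 0.34. Eif2s3y lost its call without wild type replicate 2 (edgeR adjusted p = 0.0589) and without wild type replicate 3 (0.21, 0.107), in a range of 0.000156 to 0.107. The sex list had 2 rises and 0 falls of 4, also over the list alone, and a camera adjusted p of 0.293 at a median of 0.21.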

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

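All tests weighed here were chosen after the results were seen, except the splits of the libraries for the numbers of genes and lists. In 145 quantities tested in the 4 KAT7 mutant libraries, 10 had a library far from the other libraries of its group, where chance gives about 7.2 at 1 in 20. In KAT7 mutant replicate 4, Kat7 stood at 1.22 CPM against 0.351 to 0.464 in the other mutant libraries, Rxfp3 at 0 CPM against 0.232 to 0.236, and Pmaip1 at 0.611 CPM against 1.28 to 1.40. The Rxfp3 values rest on a few reads per library, where ties between libraries can give such a flag. In KAT7 mutant replicate 3, Cpxm2 stood at 1.89 CPM against 3.39 to 3.48 and Gfap at 3.66 CPM against 1.64 to 1.97. In KAT7 mutant replicate 2, Crym stood at 8.81 CPM against 10.7 to 10.9, Nxph4 at 20.2 CPM against 17.7 to 18.1, Ntn1 at 4.41 CPM against 5.67 to 5.84, and Kdm5d at 30.6 CPM against 35.7 to 36.4. In KAT7 mutant replicate 1, Msmo1 stood at 90.4 CPM against 119 to 121.

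Chance assignment of libraries to groups is argued against for the numbers of genes, but 35 splits can give no share below 1 in 35. The real grouping was the only 1 of 35 splits to reach 3956 called genes, 1793 higher and 2163 lower, and the highest number in another split was 0 by edgeR, the only tool run on the splits. At an unadjusted p under 0.05 the real split had 5390 genes and the other splits 103 to 3188. Every other split mixes genotypes within a group, which widens the spread there, so 0 calls is no measure of a chance level. Chance assignment cannot be excluded for the number of lists: 19 of the 35 splits called at least the 6 lists of the real grouping, and the highest called 12. Taken list by list, only 1 split, the real one, had a camera p as small as that of the interferon response list (2.29e-08, the smallest of the other splits being 4.37e-07) or of the telencephalon patterning list (9.61e-06 and 3.8e-05). The real p was matched in 2 splits for synapse and ion channel genes (4.25e-06, smallest other 2.44e-06), in 3 for radial glia (1.16e-06 and 1.81e-08), in 9 for the stress response (0.000206 and 2.59e-08) and in 13 for ventral telencephalon genes (0.000171 and 1.75e-24). The other splits still differ in their share of wild type libraries, so part of what they call may come from genotype, which the 35 splits do not separate.

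Interferon response genes were lower in KAT7 mutant (median -0.734). Fewer microglia or macrophages would lower their markers too. However, the microglia and macrophage list had a median of 0.352 (0.308 to 0.504 over the refits), above the interferon list by a permutation of genes (p = 8e-05). The permutation takes genes as independent, whereas the estimated inter-gene correlation was 0.39 in the interferon list and 0.183 in the microglial list. Its p therefore does not measure the spread between animals and may be too small. A single wild type library with high levels is also argued against. The mean list level was 0.21, 0.43 and 0.61 in wild type replicates 1 to 3 and -0.38 to -0.26 in the mutant libraries. The largest camera adjusted p without each wild type library was 4.53e-06, in a range of 2.48e-12 to 0.000182 over the refits. A genotype effect and differences in genetic background or exposure between litters stay open, and the call does not hold with an estimated correlation (adjusted p = 0.416).

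The ventral telencephalon list was called higher in KAT7 mutant (median 0.44), and the oligodendrocyte lineage list, at a median of 0.36, was not called (camera adjusted p = 0.186). A lower share of cortical cells, which would raise every other cell type, stays open: the mean of these lists lay 0.25 above that of the 5 non-neural lists (endothelial, pericyte, meningeal, microglial and blood), with a permutation p of 0.11. Narrower comparisons gave a difference of 0.35 (permutation p = 0.038) without blood and of 0.58 (0.005) without blood and microglia, the last being the one run first, so the answer depends on which cell types are compared. These permutations also take genes as independent, so their p-values do not measure the spread between animals. The estimated inter-gene correlation was 0.48 in the ventral list and 0.982 in the blood list. More ventral tissue in the mutant dissections cannot be told apart, because striatal genes spread widely (SD 1.46) around a median of -0.0096, which was -0.305 to 0.103 with 1 library left out, and the 3 rises beside 4 falls came to 1 rise without KAT7 mutant replicate 1 or 3. A single mutant library as the whole source is not excluded. The largest camera adjusted p without each mutant library was 0.00344. That was without replicate 1, at a median of 0.288, and the range over the refits was 1.99e-06 to 0.0158. However, 13 of 35 splits gave a camera p as small as the real one, so a call kept in these refits cannot decide the question. Mean list levels were -0.02, 0.21 and 0.03 in KAT7 mutant replicates 2 to 4, against 0.06, -0.28 and -0.42 in wild type replicates 1 to 3. The call also did not hold with an estimated correlation (adjusted p = 0.727), and variation between dissections may account for it. Fry, which does not compare a list with other genes, gave the ventral list an adjusted p of 0.108. It gave 0.00228 to 0.0411 for the other lists that camera called.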

How the results depend on the processing

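Of the tests here, the list of KAT7 complex members without Kat7 (median 0.30, camera adjusted p = 0.117) was chosen only after the result was seen, as were the tallies of list members and of moved list medians over the alternatives. Kat7 kept its direction and call in every alternative. The numbers of genes stayed within 1.5 times of 1793 higher and 2163 lower under other scalings, filters and tools, with DESeq2 giving 1425 and 1727, and 0 called genes changed sign in any alternative. Stricter thresholds gave fewer by construction: 1034 higher at an adjusted p under 0.01, and 150 higher and 518 lower with a 2-fold change. Leaving out each library in turn gave 1273 to 1776 higher, 1826 to 2212 lower, a Kat7 log2 fold change of -7.93 to -7.17 and 6 to 8 lists. Camera with an estimated correlation called 0 lists and fry, which does not compare a list with other genes, called 11. Of 38 list counts of at least 2 rises or falls, 16 moved by over 1.5 times in some alternative, each of these also when 1 library was left out. Rises were 3 to 6 for the KAT7 complex (5 with all libraries), 3 to 5 for upper layer (3), 5 to 8 for deep layer (8), 1 to 2 for subplate (2), 1 to 3 for Cajal-Retzius (3), 1 to 4 for striatal (3), 2 to 5 for microglial (4), 1 to 7 for ribosomal protein (4) and 1 to 2 for sex genes (2). Falls were 3 to 6 for pan-neuronal (5), 2 to 5 for cortical hem (3), 1 to 5 for mitosis (4), 3 to 6 for DNA replication (5), 2 to 5 for cholesterol (4), 0 to 3 for other histone acetylation (3) and 1 to 2 for ribosomal protein genes (2). Of 32 counts of 0 or 1, 20 changed, the highest reaching 5 rises for blood and 4 for immediate early genes. Of 134 called named genes, 14 lost the call under another tool, scaling or filter and 22 without some library.

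With the replicate block, 1460 genes were higher and 1943 lower, and 8 called named genes lost the call. Among these were Jade2 (edgeR adjusted p = 0.0575) and Jade3 (0.0735). Same-numbered libraries were correlated at 0.018, 0.012 and -0.029 in their deviations from the group means, and the highest value of 0.052 was between wild type replicate 2 and KAT7 mutant replicate 3, so the numbers were not taken as pairs.

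Leaving out 1 library moved the median by over 1.5 times, without a change of sign, in 20 of 29 uncalled lists and in 1 called list (ventral telencephalon, 0.288 without KAT7 mutant replicate 1). The median of 10 uncalled lists and of 0 called lists changed sign in some alternative, and the cause was not tested. With upper-quartile factors it was -0.00569 for axon guidance and -0.00387 for endothelial genes, and with library size only -0.014 and -0.0117. With no count filter it was -0.00388 for axon guidance, 0.385 for thalamic and -0.0302 for choroid plexus genes, and with the CPM filter -0.00239, 0.0547 and -0.371, and -0.0711 for endothelial genes. With limma-voom it was -0.0588 for Cajal-Retzius, -4.16e-05 for axon guidance and 0.0157 for striatal genes, the last 0.0476 with quality weights. With the replicate block it was -0.21 for Cajal-Retzius, -0.0337 for axon guidance and -0.0744 for endothelial genes. Leaving out each library in turn gave -0.18 to 0.254 for Cajal-Retzius, -0.0473 to 0.0321 for axon guidance, -0.305 to 0.103 for striatal, -0.34 to 0.104 for thalamic, -0.254 to 0.0849 for endothelial, -0.327 to 0.00451 for pericyte, -0.0164 to 0.125 for meningeal, -0.0762 to 0.471 for immediate early and -0.0496 to 0.0528 for other histone acetylation genes.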

Other observations

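All genes and tests in this part were chosen after the results were seen. The metabotropic glutamate receptor genes Grm7 and Grm2 fell by 3.09 and 1.00 on the log2 scale and the AMPA receptor subunit gene Gria4 by 1.66, the kainate receptor gene Grik3 rose by 0.66, and the list member Gria2 stood at 0.12 (edgeR adjusted p = 0.32). Of the 4 nuclear factor I genes, transcription factors of glial and neuronal differentiation, Nfia fell by 1.23 with an edgeR adjusted p of 2.03e-12, Nfix by 0.73 and Nfib by 0.30, and Nfic stood at -0.20 (edgeR adjusted p = 0.0626). The interferon-induced GTPase genes Iigp1, Gbp3, Irgm1 and Gbp6 fell by 2.86, 2.70, 1.84 and 1.69, and Irgm2 stood at -0.47 (edgeR adjusted p = 0.273). All of these genes were picked singly, and no test of these groups was run.

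Of 228 families of genes that share a symbol stem, camera called 2. The Kat family was called with Kat7 as its only called member of 8 (adjusted p = 0.00103). The Hs family, a stem that includes heparan sulfate sulfotransferases, had 7 falls and 1 rise among 10 members, at a median of -0.45 and a camera adjusted p of 0.0125, and Hs6st3 fell by 1.80, Hs3st5 by 1.20 and Hs6st2 by 1.15 on the log2 scale. These families were not tested with an estimated correlation.

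The share of genes called higher was 6%, 8.7%, 11.7%, 14.9% and 24.2% from the shortest to the longest of 5 equal groups of tested genes, and 6.4%, 8.1%, 11.4%, 16.7% and 23% from the lowest to the highest of 5 groups by mean expression. The share called lower was 11.8% to 17.6% over the groups by length, and 16.9%, 19.4%, 16%, 13.9% and 12.9% from the lowest to the highest expression. Rises by 2-fold or more went the other way, at 93, 30, 19, 4 and 4 genes from the lowest to the highest expression. Median log2 fold changes of the groups were -0.08 to 0.04 by expression and -0.03 to 0.06 by length. The contributions of length, of expression and of the greater ease of calling changes at higher counts were not separated.

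Among 494 genes that fell by 2-fold or more and were placed on the GRCm38.p6 gene table, 53 neighbouring pairs were found, against a mean of 18.7 and a maximum of 35 in 10000 shuffles (permutation p = 1e-04, the smallest they can give). Among 142 genes that rose by 2-fold or more there were 10 pairs (mean 1.5, maximum 8, permutation p = 1e-04), and 3 with no shared stem, zinc finger or predicted gene (mean 1.3, permutation p = 0.1). For the falls, reads shared between neighbouring paralogs are argued against as the whole source by 32 pairs with no shared stem, zinc finger or predicted gene (mean 15.4, maximum 31), and foreign DNA around the targeted locus by 50 pairs without Kat7 and its 100 nearest tested genes (mean 18.3, maximum 36). Near Kat7 itself such DNA cannot be told apart: 35 of the 100 nearest genes were called against 281 of 944 on the rest of the chromosome (odds ratio 1.27, 95% interval 0.8 to 2, Fisher's exact p = 0.3), with 18 lower and 17 higher near Kat7 against 158 and 123 on the rest, although Samd14, Pdk2, Itga3 and Fam117a beside Kat7 fell. The shuffles took all placed genes as exchangeable and were not matched for expression. Of the falls by 2-fold or more, 304 lay in the lowest of 5 groups of tested genes by mean expression. Clustering of genes of similar expression could raise every count of pairs and was not tested, which limits both arguments. Shared regulation of neighbouring genes and differences in genetic background elsewhere in the genome may both give such pairs, and neither was tested.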
